A study of Roseovarius tolerans with 12 samples.

How the data were processed

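RNA was measured in 12 libraries of *Roseovarius tolerans* EL-164, 3 in each of 4 groups, grown with 12.5 µM myricetin or with DMSO alone and sampled in exponential or early stationary phase. Per the labels, cultures started at an OD600 of 0.01 and grew at 30 °C and 40 rpm in 25 mL of medium in 125 mL flasks. Samples of 3 mL were kept in RNA stabilisation solution for 24 hours at 4 °C, and triplicates are biological. The p-values therefore measure the spread between cultures. Whether an exponential and a stationary sample with the same number came from the same flask was not stated. The main fit treats such samples as independent, which would be wrong for phase and interaction if they shared a flask, and a block by culture was an alternative.

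The deposited values are raw counts per gene from featureCounts, which the authors ran for each library, per the file headers. The header gives release 2.0.6, the gene feature, reverse-strand counting (setting 2), both ends mapped, no chimeric pairs and a minimum mapping quality of 30, with the gene models of assembly ASM2888539v1. The submitters' processing notes name FastQC, Trimmomatic 0.39, HISAT2, SAMtools, featureCounts 2.0.6 and DESeq2 1.38.0, and the header's folder names give HISAT2 2.2.1. The option that counts read pairs rather than reads was not among the header's settings. Of 1373 counts between 1 and 20, 56% were even, so the values do not settle whether a count is a read or a pair. The minimum mapping quality removes most reads that fit repeated sequences, so copies of insertion elements (*istA*, *istB*, *tnpC*) are measured only through the parts in which they differ. Counting used strand, so antisense neighbours are kept apart.

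Gene symbols came from a RefSeq gene table of the same assembly, which gives symbols but no product names. Of 3866 identifiers 3852 matched, 14 did not, 3765 had identical coordinates and 818 had a symbol (745 distinct). Genes without a symbol are named by locus tag. All 48 structural RNA genes stayed in the library totals, and no column of the files was left unused.

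Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr were kept (3817, with 49 removed), and libraries were scaled with TMM factors between 0.957 and 1.1. A single quasi-likelihood model (glmQLFit, glmQLFTest) with 4 group means was fitted to all 12 libraries and gave 5 contrasts: myricetin against DMSO at each phase, stationary against exponential phase for each treatment, and their interaction. The Benjamini-Hochberg adjusted p threshold was 0.05. Standard errors are the log2 fold change divided by the square root of the F statistic. Principal components used log2 CPM with a prior count of 2. Replicates were compared by a chi-square test of their counts, and no pair within a group agreed within sampling noise.

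Before the data were examined, the tests, 21 gene lists, the alternatives and the rule for named genes were fixed. The rule takes the 10 largest rises and 10 largest falls in each treatment comparison (8 and 8 for phase with DMSO, repeated with myricetin) among genes past the threshold, with at least 10 CPM in the higher group and no overlap between the 3 and 3 libraries. Chance gives no overlap in 10% of genes. It adds the 10 genes with the lowest p for the interaction, up to 3 members of each list per treatment comparison and the 5 longest runs in each direction. With no product names, the rule and the lists were applied to genes with a symbol, and 11 of the 21 lists had fewer than 5 members and no set test. Another 20 lists were written from the symbols alone, before any test. Lists were tested with camera (limma 3.58.1), with a preset correlation of 0.01 and again with an estimated one, adjusted within the fixed and the added lists separately. A run was at least 4 neighbouring genes on 1 strand called in 1 direction, compared with 1000 shuffles of the calls.

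The labels number the replicates alike in all groups. Deviations from the group means correlated between same-numbered libraries across treatments, at 0.282, 0.248 and 0.382 in exponential phase and 0.323, 0.303 and 0.62 in stationary phase, each the highest for its library. The numbers therefore pair the samples for the treatment comparisons, and a fit with the replicate number as a block was an alternative. Between phases the correlations ran from -0.0619 to 0.512.

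Each step was tested on simulated counts drawn from the real means and library sizes with 200 changed genes of at least 10 CPM, besides a planted list and a planted run. Genes were drawn independently of each other, with the same mean in all groups before the changes and no shift between replicate numbers. The real libraries had such shifts, so the rates that follow may not hold for them. For myricetin in exponential phase, over 3812 genes, the test recovered 92.5% of 1.5-fold and 100% of 2-fold changes, with 4.35% false calls. For stationary phase, over 3811 genes, it recovered 86.6% and 100%, and for the interaction, over 3808 genes, 52.2% and 97%. For phase the 1.5-fold values were 89.6% with DMSO and 91% with myricetin, each over 3810 genes. Alternatives were RLE factors, library totals without factors, no expression filter, a filter of 10 CPM in 3 libraries, DESeq2 1.42.0, removal of structural RNA genes, a 2-fold minimum, each library left out in turn, replicate blocks and separate fits of 6 libraries. Thinning all libraries to the smallest total of 20650636 counts, leaving out the 4 libraries numbered 3 and testing the heme list without *hemP* and the iron list without *hemP*, *bfr* and *hmuQ* were added after the data were seen.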

Results

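*Roseovarius tolerans* EL-164 is a marine alphaproteobacterium of the roseobacter group. Cultures received either 12.5 µM myricetin, a plant flavonol, or only the solvent, with 1% DMSO in both. RNA was collected at an OD600 near 0.3 (exponential phase) and near 0.75 (early stationary phase). The 4 groups held 3 biological replicates each, giving 12 strand-specific, rRNA-depleted RNA-seq libraries. Whether the same flasks were sampled at both phases was not stated, so the number of separate cultures is not known. Read counts were available for 3866 genes on 1 chromosome, and 3817 were tested. Counts assigned to genes totalled 20650636 to 22421287 in the exponential libraries and 40412463 to 48624572 in the stationary libraries. These totals differed between phases by 2.1 times on average, and whether by depth or by the counting unit is not known. Ribosomal RNA made up 0.224% to 1.09% of counts. The first principal component held 38.7% of the variance and separated the phases. The next held 32.1% and separated myricetin from DMSO. The component after that held 9.33% and set the libraries numbered 3 apart from those numbered 1 and 2. Levels are normalised read counts (CPM, scaled to library size) ± SD with n = 3, log2 fold changes carry their standard error (SE), and adjusted p-values come from edgeR's quasi-likelihood test. Several symbols belong to more than 1 gene. Here *ppk2* is PVU19_RS12420, *hemA* PVU19_RS10535, *gap* PVU19_RS06895, *dctP* PVU19_RS16825, *moaA* PVU19_RS17385, *grxD* PVU19_RS17425, *fdxA* PVU19_RS13820, *fghA* PVU19_RS11090, *lpdA* PVU19_RS03580 and *sucD* PVU19_RS03550. Other copies could differ, such as the *gap* gene PVU19_RS06905, which fell between phases with DMSO (adjusted p = 5.811e-06) where PVU19_RS06895 rose.

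The first comparison asked which genes respond to myricetin in exponentially growing cells. Among genes with a symbol that met the rule for named genes, *hemP*, *bfr* and *hmuQ* rose most. The last 2 were the only members with a symbol of the iron uptake and storage list fixed beforehand. *hemP*, a small hemin-uptake-associated protein, went from 64.8 ± 13 to 1345 ± 66.7 CPM, a 20.8-fold rise (log2 fold change 4.38 ± 0.13, adjusted p = 3.57e-13). *bfr*, which encodes the iron-storage protein bacterioferritin, rose 7.51-fold (2.91 ± 0.10, adjusted p = 2.5e-12), from 77.4 ± 10 to 581 ± 50.2 CPM. *hmuQ*, named for heme breakdown, rose 2.32-fold (1.22 ± 0.13, adjusted p = 9.23e-06). Under the same rule, genes for the compatible solute ectoine, *ectB* and *ectA*, and for the catalase-peroxidase *katG* fell most.

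In all, 585 of the 3817 genes passed an adjusted p of 0.05 in exponential phase, 247 higher and 338 lower with myricetin. Of these, 65 changed at least 2-fold, 38 upward and 27 downward. Scaling to library totals turned the balance of calls, to 351 higher and 243 lower, without giving any gene called with TMM factors the opposite sign. The count was 348 without replicate 2 of the myricetin group and 381 without replicate 1 of the DMSO group.

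*hemP* and *bfr* lie on the minus strand at 2546794 to 2546958 and at 2545581 to 2546066 of the chromosome (assembly ASM2888539v1). The pair of genes between them, PVU19_RS12575 and PVU19_RS12580, were chosen for mention after their values were seen. They rose as well, with log2 fold changes of 4.14 ± 0.19 and 4.53 ± 0.12. A list of 11 iron-sulfur cluster genes and iron regulators, written after the gene symbols were known but before any test, had 6 members higher and 2 lower. Camera placed this list above other genes (adjusted p = 2.3e-10 with a preset correlation of 0.01, and adjusted p = 0.0304 with an estimated correlation). The list held *hemP*, *bfr* and *hmuQ* and rested on them: without these 3, a setting added after the data were seen, 3 of 8 genes were higher and 2 lower, and adjusted p = 0.856. Its other called members included *fdxA*, a ferredoxin, at 0.58 ± 0.09 and *mbfA*, a membrane-bound ferritin-like iron exporter, at -0.70 ± 0.10. The list written for heme biosynthesis held 10 genes with *hem* symbols, *hemP* among them, though it is not a biosynthesis gene. Besides *hemP*, *hemH* (ferrochelatase) was called, at 0.31 ± 0.09 (adjusted p = 0.0291, and 0.0508 with a replicate block). That call also ended without any 1 exponential library other than replicate 1 of the myricetin group (adjusted p from 0.057 to 0.0796). The list's camera value (adjusted p = 0.00763, and 0.267 with an estimated correlation) rested on *hemP*: without it, a setting added after the data were seen, adjusted p = 0.883 and the median was 0.02.

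Other rising genes in exponential phase included *moaA*, which acts in molybdenum cofactor synthesis, 1.89-fold (0.92 ± 0.11), and *adh*, an alcohol dehydrogenase, 1.87-fold (0.90 ± 0.17). *tpiA*, triose-phosphate isomerase, rose 1.75-fold (0.81 ± 0.09). *xoxF5*, a lanthanide-dependent methanol dehydrogenase, rose 1.66-fold (0.73 ± 0.12), *rpoZ* of RNA polymerase 1.47-fold (0.56 ± 0.13) and *sucC* of succinyl-CoA ligase 1.45-fold (0.53 ± 0.12). Their adjusted p-values ran from 9.97e-06 for *tpiA* to 0.00692 for *rpoZ*.

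Among the falling genes, *ectB* went from 171 ± 8.11 to 61.9 ± 17.2 CPM (-1.46 ± 0.21, adjusted p = 0.000132). *ectA* went from 35.2 ± 2.06 to 13.1 ± 2.73 CPM (-1.43 ± 0.16, adjusted p = 1.08e-05). *katG* fell from 2224 ± 16.4 to 1017 ± 149 CPM (-1.13 ± 0.12, adjusted p = 6.31e-06). Subunits of the cbb3-type cytochrome oxidase, a terminal oxidase with high oxygen affinity, were lower: *ccoO* by -0.95 ± 0.11 and *ccoP* by -0.88 ± 0.13. The polyphosphate kinase gene *ppk2* changed by -0.94 ± 0.15, the copper nitrite reductase gene *nirK* by -0.77 ± 0.15 and the aconitase gene *acnA* by -0.76 ± 0.13. The transporter gene *dctP* changed by -0.72 ± 0.12. The highest adjusted p-value among these 6 genes was 0.002, for *nirK*.

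The gene lists fixed beforehand did not stand apart from other genes in exponential phase. Of 21 lists, 10 had at least 5 members with a symbol, and camera gave adjusted p-values from 0.41 to 0.958 for these. Of 13 oxidative stress genes, 2 were higher (*grxD*, a glutaredoxin, and *trxB*, thioredoxin reductase) and *katG* was lower, the same numbers as adjusted over the list alone. The *trxB* call (0.27 ± 0.08, adjusted p = 0.0318) ended with a replicate block (adjusted p = 0.0517) and without replicate 1 or 2 of either group (adjusted p from 0.0613 to 0.135). The *grxD* call (0.75, adjusted p = 0.0169) ended without replicate 1 of the DMSO group (adjusted p = 0.0715) or replicate 2 of the myricetin group (0.056). Of 21 respiration and ATP synthase genes, 1 was higher and 5 lower, and adjusted over the list alone also 1 and 5. Of 12 central carbon genes, 3 were higher and 4 lower (4 and 4 adjusted over the list alone), with *acnA* and the citrate synthase gene *gltA* (-0.41 ± 0.09) down and *sucC* up. Of 21 nitrogen and phosphate genes, 1 was higher and 5 lower (1 and 6 adjusted over the list alone). *glnA*, glutamine synthetase, changed by -0.48 ± 0.10 and *gltB*, glutamate synthase, by 0.38 ± 0.09. Of 5 polyhydroxyalkanoate and storage genes, 3 were lower (3 adjusted over the list alone). None of 14 chaperone and protease genes was called by edgeR, also 0 adjusted over the list alone, with 3 at an unadjusted p below 0.05 and 1 called by DESeq2. Of 50 ribosomal protein genes 2 were lower (0 adjusted over the list alone), of 27 photosynthesis genes 1 was higher and 1 lower (1 and 0 adjusted over the list alone), of 8 DMSP and sulfur genes 2 were lower (2 adjusted over the list alone), and of 20 DNA repair genes 1 was higher (1 adjusted over the list alone). Many of these counts changed when 1 library was left out. Higher oxidative stress genes ran from 0 (without replicate 1 of the DMSO or replicate 2 of the myricetin group) to 3, and chaperones from 0 to 3. The higher DNA repair count was 0 without replicate 1 of the DMSO or replicate 2 of the myricetin group. The lower DMSP and sulfur count was 0 without replicate 1 or 3 of the DMSO group. For ribosomal proteins the lower count was 0 without replicate 2 of the myricetin or any replicate of the DMSO group and otherwise up to 4, and for photosynthesis 0 without replicate 1 of the DMSO or replicate 2 or 3 of the myricetin group. The lower counts ran from 2 to 6 for respiration, from 1 to 4 for nitrogen and phosphate and from 2 to 4 for central carbon, where the higher count ran from 1 to 3. The single measured members of the aromatic degradation (*pcaD*), flagella (*fliK*) and secretion (*cpaB*) lists were not called in either phase, with adjusted p-values from 0.153 to 0.836. Median, mean and test did not share 1 sign for the oxidative stress and central carbon lists in exponential phase and for the DMSP, DNA repair and storage lists in stationary phase.

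Changed genes lay in runs along the chromosome. There were 28 runs of at least 4 neighbouring same-strand genes called in 1 direction, 12 higher and 16 lower, while 1000 shuffles of the calls gave 0.092 runs on average and 2 at most. The longest rising run, PVU19_RS04935 to PVU19_RS04970 (997640 to 1006452), held 8 genes with a median log2 fold change of 1.12. The run of 6 genes PVU19_RS06195 to PVU19_RS06220 (1260331 to 1264058) had a median of 3.06, an 8.32-fold rise. A run of 6 genes that included *sufC* of iron-sulfur cluster assembly had a median of 0.41, and one of 6 genes with *xoxF5* and *fghA* a median of 0.94. The 5 longest falling runs all lay between 2983313 and 3116806 on the plus strand. The longest of these, PVU19_RS14800 to PVU19_RS14855, held 12 genes with a median of -1.09. The runs that followed it in length held 8, 7, 7 and 7 genes, with medians of -0.92, -0.83, -1.04 and -0.84.

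**Figure D1:**
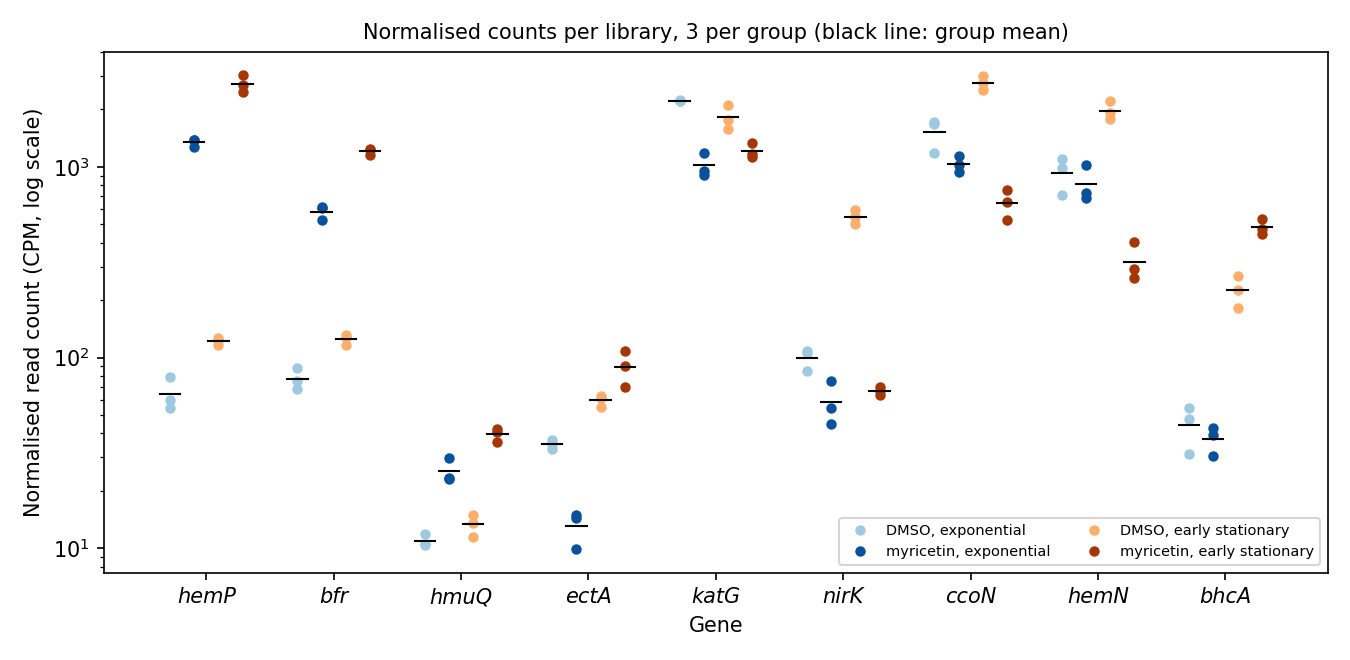
Normalised read count (CPM, log axis) of 9 genes in each of the 12 libraries, coloured by treatment and phase, with black lines for group means of 3 libraries. *hemP* and *bfr* were higher with myricetin at both phases, and *nirK* was at 67 CPM with myricetin against 547 CPM with DMSO in early stationary phase.

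The same comparison in early stationary phase asked which genes respond to myricetin as growth slows. *hemP* and *bfr* were again higher, *hemP* by 22.3-fold (4.48 ± 0.13, adjusted p = 2.4e-13) and *bfr* by 9.6-fold (3.26 ± 0.10, adjusted p = 4.69e-13). The largest falls among genes with a symbol that met the rule for named genes were in *nirK*, *hemN*, *ppk2*, *ccoG* and *ccoN*. *nirK* fell from 547 ± 47 to 67.0 ± 3.06 CPM, 8.17-fold lower (-3.03 ± 0.15, adjusted p = 2.83e-10). *hemN*, which encodes an oxygen-independent coproporphyrinogen oxidase, fell from 1971 ± 215 to 319 ± 76.3 CPM (-2.63 ± 0.19, adjusted p = 2.68e-08). *ccoN*, the catalytic subunit of the cbb3 oxidase, fell from 2758 ± 227 to 645 ± 115 CPM (-2.10 ± 0.15, adjusted p = 1.84e-08).

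In this phase 1245 genes were called, 626 higher and 619 lower, of which 201 changed at least 2-fold (71 upward, 130 downward). The balance of calls depended on the setting, with 573 higher and 653 lower without structural RNA genes, 675 and 530 with the 10 CPM filter, and 725 and 516 with all libraries thinned to the smallest total. The last was added after the data were seen. The count was 829 without replicate 1 of the myricetin group, and 719 when all 4 libraries numbered 3 were left out, a setting added after the data were seen.

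With *ccoN*, the genes *ccoG* (-2.21 ± 0.17), *ccoO* (-1.79 ± 0.12) and *ccoP* (-1.56 ± 0.13) of the same cluster fell. Also lower were *ppk2* (-2.41 ± 0.15, from 1789 ± 259 to 337 ± 40.6 CPM) and *hemA*, 5-aminolevulinate synthase (-1.26 ± 0.10). *gap*, glyceraldehyde-3-phosphate dehydrogenase, changed by -1.24 ± 0.13 and *serA*, which starts serine synthesis, by -1.15 ± 0.13. Their adjusted p-values ran from 4.71e-09 for *ppk2* to 5.42e-06 for *serA*. *fnrL*, a regulator of genes for low oxygen, was higher, by 0.78 ± 0.09 (adjusted p = 3.47e-06). The list of 13 cytochrome c maturation and terminal oxidase genes had 3 members higher and 4 lower, with a median of -0.08. The 4 lower members were *ccoG*, *ccoN*, *ccoO* and *ccoP*, and the higher count ran from 1 to 4 when 1 library was left out. Camera placed the list below other genes (adjusted p = 0.0288, 0.051 without replicate 3 of the myricetin group, and adjusted p = 0.592 with an estimated correlation). The list was not tested again without the *cco* genes.

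Rising genes in stationary phase included *moaA*, 3.87-fold (1.95 ± 0.11, adjusted p = 7.17e-10), *grxD*, 3.42-fold (1.77 ± 0.18, adjusted p = 1.3e-06), and *hmuQ*, 2.98-fold (1.57 ± 0.13, adjusted p = 8.1e-08). *adh* rose 2.44-fold (1.29 ± 0.18). *metF*, methylenetetrahydrofolate reductase, went from 1974 ± 907 to 4678 ± 452 CPM (1.24 ± 0.22, adjusted p = 0.000377). The *bhc* genes, which encode the beta-hydroxyaspartate cycle of glyoxylate assimilation, rose as a group: all 5 were called. *bhcA* rose by 1.10 ± 0.18, *bhcD* by 0.92 ± 0.17 and *bhcB* by 0.86 ± 0.13. Camera's adjusted p for this list, also written after the symbols were known, was 0.00536, and adjusted p = 0.592 with an estimated correlation. The iron-sulfur and iron regulator list again had 6 higher and 2 lower members (camera adjusted p = 4.09e-07, and adjusted p = 0.146 with an estimated correlation), and adjusted p = 0.849 without *hemP*, *bfr* and *hmuQ*.

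None of the 10 lists fixed beforehand was called in this phase, with camera adjusted p-values from 0.149 to 0.99. For the lowest, the ribosomal proteins, adjusted p = 0.0158 without replicate 2 of the myricetin group and 0.0387 without replicate 3 of the DMSO group, while adjusted p = 0.807 with an estimated correlation over all libraries. Of 50 ribosomal protein genes 13 were lower and 0 higher (13 and 0 adjusted over the list alone), for example *rpmG* at -0.64 ± 0.11 and *rpmB* at -0.57 ± 0.07. Of 27 photosynthesis and carotenoid genes 1 was higher and 8 lower (1 and 8 adjusted over the list alone), including *bchE* of bacteriochlorophyll synthesis at -1.60 ± 0.18 and *pufQ* at -1.21 ± 0.27. Of 21 nitrogen and phosphate genes 4 were higher and 8 lower (4 and 8 adjusted over the list alone), with *gltB* at 0.70 ± 0.09 and the phosphate transporter genes *pstA* at -0.83 ± 0.12 and *pstB* at -0.79 ± 0.11. Respiration and ATP synthase genes went both ways, 6 higher and 6 lower of 21 (8 and 6 adjusted over the list alone). Of 13 oxidative stress genes 3 were higher and 1 lower (3 and 1 adjusted over the list alone), with *katG* again lower (-0.58 ± 0.12). Of 12 central carbon genes 3 were lower (3 adjusted over the list alone), among them *pdhA* of pyruvate dehydrogenase at -1.02 ± 0.10. Of 14 chaperone genes 2 were higher and 1 lower (2 and 1 adjusted over the list alone). Of 8 DMSP and sulfur genes 1 was higher and 2 lower (1 and 2 adjusted over the list alone). The higher one, *dddP*, encodes a DMSP lyase (0.67 ± 0.08). Of 20 DNA repair genes 1 was higher and 3 lower (1 and 3 adjusted over the list alone), and of 5 storage genes 1 was higher and 1 lower (1 and 1 adjusted over the list alone). Without 1 library the higher chaperone count ran from 0 (without replicate 2 or 3 of the DMSO or replicate 1 or 3 of the myricetin group) to 3. Higher DNA repair genes ran from 0 (without replicate 1 of the myricetin group) to 3, and the higher photosynthesis count was 0 without replicate 3 of the DMSO or replicate 1 or 3 of the myricetin group. The ranges were 8 to 16 for lower ribosomal protein genes, 3 to 7 for lower photosynthesis genes, 3 to 8 higher and 3 to 6 lower for respiration, 1 to 5 for higher nitrogen and phosphate genes, 1 to 3 for higher oxidative stress genes and 1 to 2 for lower DMSP and sulfur genes.

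There were 47 runs in stationary phase, 21 higher and 26 lower, against 1.7 on average and 8 at most in 1000 shuffles. The longest, PVU19_RS14950 to PVU19_RS15030 (3026085 to 3043944, minus strand), held 17 genes including *darG* and *darT*, a toxin-antitoxin pair, with a median of -0.58. The 12-gene run PVU19_RS14800 to PVU19_RS14855 had a median of -1.34. The 8-gene run PVU19_RS04935 to PVU19_RS04970 was again the longest rising run, with a median of 1.14. A 6-gene run with *tolQ*, *tolR*, *tolB*, *pal* and *ybgF* of the cell envelope Tol-Pal system had a median of 0.41. In a 7-gene run, PVU19_RS11875 to PVU19_RS11905 (2403350 to 2411416), the median was 0.81 in stationary and -0.32 in exponential phase, and all 7 genes passed the interaction test.

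Lower genes were gathered in 1 part of the chromosome at both phases. The position was chosen after the values were seen, as the longest stretch of 50000-base windows in which at least 25% of the tested genes were lower in both comparisons. It ran from 2950001 to 3150000 and held 211 tested genes, of which 90 were lower in exponential phase and 134 in stationary phase. This is 42.65% and 63.51% of them, against 6.877% and 13.45% of the genes elsewhere. The rule guaranteed at least 25% inside, so this contrast describes the segment and is no test. Between *cobF* and *cobW* (3072039 to 3085591) lay 8 cobalamin biosynthesis genes with a median log2 fold change of -0.08 in exponential and 0.27 in stationary phase.

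**Figure D2:**
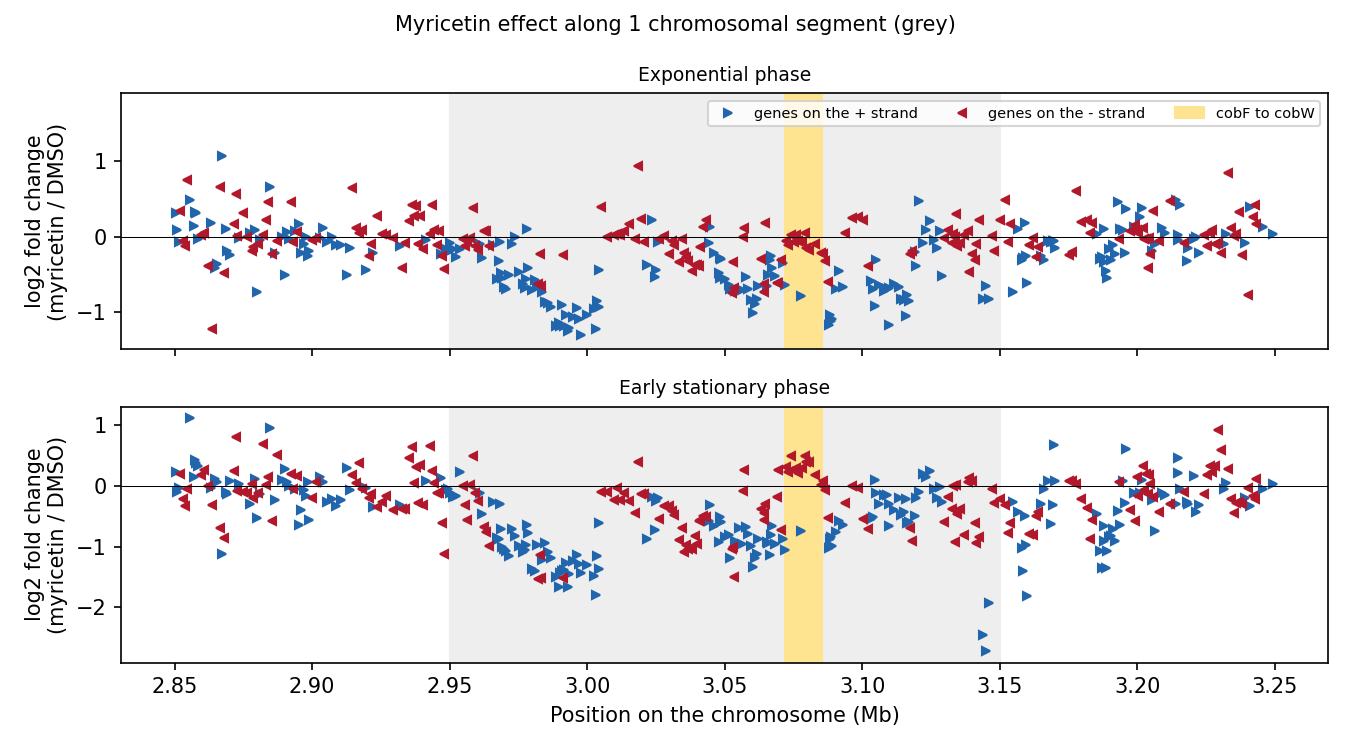
Log2 fold change of myricetin over DMSO against chromosomal position in Mb for each tested gene, with triangles pointing along the gene's strand, exponential phase above and early stationary phase below. Most genes in the grey stretch lie below 0, while the 8 *cob* genes in the yellow band have a stationary median of 0.27.

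**Figure D3:**
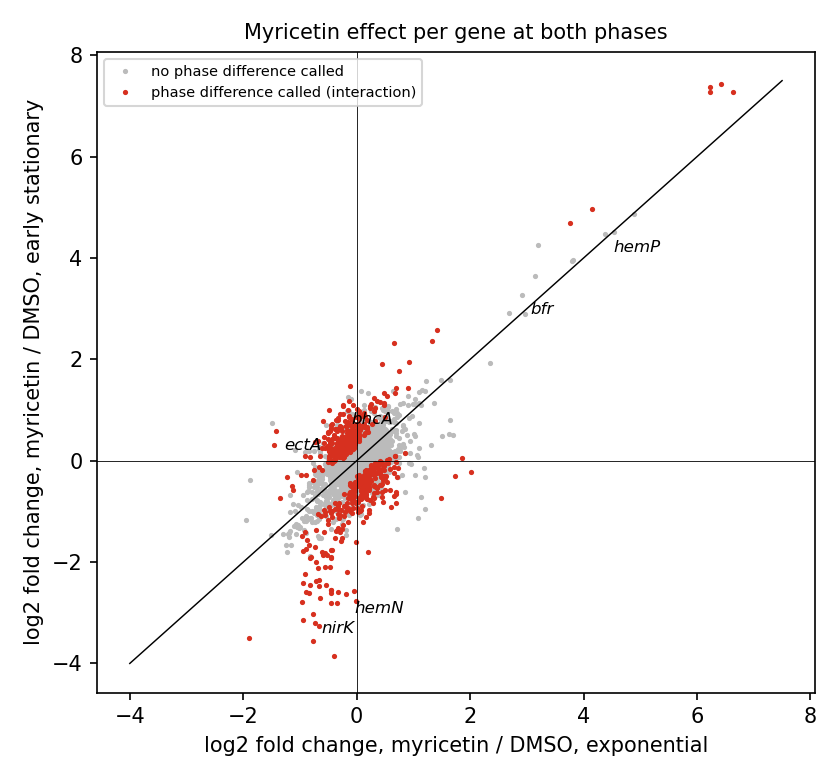
Log2 fold change of myricetin over DMSO for each tested gene, exponential phase on the horizontal and early stationary phase on the vertical axis, with the diagonal of equal change. Red points are the 594 genes whose change differed between phases, and *nirK* and *hemN* lie far below the diagonal.

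The interaction of treatment and phase asks whether the myricetin effect depends on growth phase. It did for 594 genes, 298 with a higher and 296 with a lower log2 fold change in stationary phase. The effect on *nirK*, *hemN*, *ccoG* and *ccoN* was more negative in stationary phase, with *hemN* and *ccoG* not called in exponential phase, while *ectA* and *ectB* fell only in the exponential comparison. The difference for *ectA*, stationary minus exponential, was 2.01 ± 0.22 (adjusted p = 1.46e-05), and that for *nirK* was -2.26 ± 0.21 (adjusted p = 2.7e-06). The 5 *bhc* genes all had a more positive effect in stationary phase (camera adjusted p = 5.33e-06, and adjusted p = 0.275 with an estimated correlation).

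Of 594 genes, 49 were called higher at 1 phase and lower at the other, 85 moved the same way at both, 323 were called in stationary phase alone and 92 in exponential phase alone. *dddP* was among the first kind, at -0.28 ± 0.08 in exponential phase (adjusted p = 0.0302, 0.0539 with a replicate block, 0.119 with library totals, and 0.0669 to 0.112 without any 1 exponential library other than replicate 1 of the myricetin group) and 0.67 ± 0.08 in stationary phase. Lists with a called shift were heme biosynthesis (downward, adjusted p = 0.0215, 0.0093 without *hemP*, and adjusted p = 0.285 with an estimated correlation), cobalamin biosynthesis (upward, adjusted p = 0.00946, and adjusted p = 0.31 with an estimated correlation) and histidine biosynthesis (downward, adjusted p = 0.00946, and adjusted p = 0.244 with an estimated correlation). The phases shared 108 genes called higher and 179 called lower with myricetin, against 40.5 and 54.8 for independent lists, and across genes the log2 fold changes correlated with r = 0.651 and rho = 0.326, where genes are not independent replicates. The interaction count was 390 with a replicate block by culture, 379 without replicate 3 of the myricetin stationary group and 216 without the 4 libraries numbered 3. Scaling to library totals gave 200 more positive and 385 more negative differences.

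Early stationary against exponential phase shows the course of growth itself, first with DMSO alone. Among genes with a symbol that met the rule for named genes, *rocF*, *clpB* and *nirK* rose most and *adh* fell most. *rocF*, arginase, rose 5.71-fold (2.51 ± 0.08, adjusted p = 7.57e-12), from 82.2 ± 0.741 to 470 ± 29.6 CPM. *clpB*, a disaggregating chaperone, rose 5.56-fold (2.47 ± 0.26, adjusted p = 1.28e-06). *nirK* rose 5.5-fold (2.46 ± 0.15, adjusted p = 6.62e-09). *adh* fell 9.41-fold (-3.23 ± 0.19, adjusted p = 4.59e-09).

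With DMSO, 1656 genes were called, 943 higher and 713 lower in stationary phase, and 268 changed at least 2-fold (220 upward). The excess of higher genes depended on scaling, with 877 higher and 801 lower by RLE factors and 831 and 824 by library totals. The stationary libraries also had the higher count totals. With all libraries thinned to the smallest total, a setting added after the data were seen, 1651 genes were called, and 1545 of the 1656 were among them, none with the opposite sign. *bhcA* (2.35 ± 0.19), *dctP* (2.33 ± 0.13), *gap* (2.10 ± 0.14) and the phosphonate genes *phnC* (2.02 ± 0.22) and *phnF* (1.85 ± 0.15) also rose. Falling genes were *metF* (-1.54 ± 0.22), *sdhD* (-1.38 ± 0.08) and *sdhA* (-1.25 ± 0.09) of succinate dehydrogenase, *sucC* (-1.37 ± 0.12) and *sucD* (-1.13 ± 0.14) of succinyl-CoA ligase, and *odhB* (-1.26 ± 0.13) and *lpdA* (-1.06 ± 0.09), which serve the 2-oxoglutarate dehydrogenase complex. Of 14 chaperones and proteases 11 were higher and 0 lower (11 and 0 adjusted over the list alone; camera adjusted p = 4.4e-05). Of 12 central carbon genes 2 were higher and 9 lower (3 and 9 adjusted over the list alone; adjusted p = 0.000654), and of 21 respiration genes 4 were higher and 14 lower (4 and 14 adjusted over the list alone; adjusted p = 0.000654). Of 50 ribosomal protein genes 25 were lower and 1 higher (25 and 1 adjusted over the list alone; adjusted p = 6.43e-05). Nitrogen and phosphate genes had 16 of 21 higher and 1 lower (17 and 2 adjusted over the list alone; adjusted p = 0.000916), and oxidative stress genes 6 of 13 higher and 1 lower (6 and 2 adjusted over the list alone; adjusted p = 0.0288). With an estimated correlation none of these 6 lists kept its call, with adjusted p between 0.273 and 0.345. The oxidative stress call also ended without replicate 1 of the DMSO stationary group (adjusted p = 0.0563).

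With myricetin the genes named above for DMSO again moved in the same direction between phases, most of them past the threshold. *rocF* rose 7.81-fold (2.96 ± 0.08, adjusted p = 3.99e-13) and *clpB* 6.16-fold (2.62 ± 0.26, adjusted p = 6.41e-07). *bhcA* rose 12.9-fold (3.69 ± 0.20, adjusted p = 1.04e-09). For *nirK* the log2 fold change was 0.20 ± 0.15 (adjusted p = 0.274), and 0.42 with adjusted p = 0.00782 without replicate 2 of the myricetin exponential group. *sucC* fell 3.71-fold (-1.89 ± 0.12) and *sucD* 3.43-fold (-1.78 ± 0.14).

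With myricetin 1789 genes were called, 938 higher and 851 lower, and 298 changed at least 2-fold (236 upward). Scaling to library totals gave 744 higher and 1185 lower, with the median of all genes at -0.113 against -0.00215 with TMM factors. More genes were also lower than higher with RLE factors (901 higher, 920 lower), no filter (876 and 985), DESeq2 (932 and 976) and without replicate 3 of the myricetin exponential group (864 and 944). *dctP* (2.77 ± 0.13), *phnF* (2.37 ± 0.15), *gap* (1.36 ± 0.14) and *phnC* (1.24 ± 0.21) rose, and *adh* (-2.85 ± 0.18), *odhB* (-1.61 ± 0.13), *lpdA* (-1.42 ± 0.09), *sdhA* (-1.31 ± 0.09) and *sdhD* (-1.14 ± 0.08) fell. *metF* changed by -0.60 ± 0.21 (adjusted p = 0.0298, and 0.0534 by DESeq2). That call ended without replicate 1 or replicate 3 of either myricetin group (adjusted p from 0.0531 to 0.0931). All 5 *bhc* genes rose (camera adjusted p = 1.23e-11, and adjusted p = 0.123 with an estimated correlation). Of 50 ribosomal protein genes 34 were lower and 1 higher (38 and 1 adjusted over the list alone; adjusted p = 1.07e-06, and adjusted p = 0.231 with an estimated correlation). The 2 treatments shared 598 genes called higher and 412 called lower between phases, against 232 and 159 for independent lists.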

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

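The tests on the growth transition and on count totals, the splits of pairs for the interaction and the choice of the 8 genes came after the results were seen.

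The myricetin effect differed between phases, by edgeR's interaction test, for 594 genes. Among the named genes the log2 effect was lower in stationary than in exponential phase for *hemN* (difference -2.44), *nirK* (-2.26), *ccoG* (-2.04), *ccoN* (-1.54), *ppk2* (-1.47), *pdhA* (-1.04), *hemA* (-1.03), *xoxF5* (-0.88), *ccoO* (-0.84), *gap* (-0.75), *ccoP* (-0.67), *rpoZ* (-0.60) and *sucC* (-0.52). It was higher for *ectA* (2.01), *ectB* (1.78), *bhcA* (1.35), *moaA* (1.03), *grxD* (1.02), *bhcB* (0.99), *dddP* (0.95), *metF* (0.94), *bhcC* (0.88), *bhcD* (0.87), *acnA* (0.58) and *katG* (0.54). With the 6 same-numbered pairs kept whole and each given its own level, the myricetin effect differed between phases for 624 genes. The pairs have 10 splits, too few for a share under 0.05, and 1 of 10 gave as many, the highest other giving 0. For each of the other 4 comparisons 10 splits of the 6 libraries exist, also too few. The real counts of 585, 1245, 1656 and 1789 were reached by 1 of 10 splits each, and the highest other split gave 0 in every case.

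With DMSO, *nirK*, *ccoN*, *ccoO*, *ccoP*, *ccoG*, *hemN*, *hemA* and *ppk2* were higher in stationary phase (median log2 change 1.12), and with myricetin their median change was 0.03. Myricetin cultures sampled earlier in the growth transition would have levels between those of the DMSO phases, if levels move steadily. Past the threshold, 7 of the genes were lower in myricetin stationary than in DMSO exponential cultures, from -0.571 ± 0.145 for *nirK* to -1.544 ± 0.187 for *hemN*. The genes were picked for low stationary levels with myricetin, so this count is partly a product of that choice. *hemN* and *ccoG* (-0.681 ± 0.161) were not called lower with myricetin in exponential phase (-0.19 and -0.17). For *hemN* and *ccoG* the values argue against earlier sampling as the whole cause. For *hemA* it stays open (-0.108, adjusted p = 0.379, and 0.036 without replicate 1 of the DMSO exponential group). A lag that adds to the pattern stays open too. *ccoO*, *ppk2*, *ccoP*, *nirK* and *ccoN* were already lower with myricetin in exponential phase (log2 fold changes from -0.95 to -0.56). For these, a lag from that lower start would also give levels below those of DMSO exponential cultures, so the comparison cannot decide. Over the 935 other genes called higher with DMSO, the ratio of the change with myricetin to that with DMSO had a median of 0.872 and quartiles of 0.292 and 1.27. Over the 713 genes called lower with DMSO, the median was 0.692 and the quartiles were 0.276 and 1.1. These genes were chosen by their DMSO change, which is the divisor. A median ratio below 1 can come partly from that choice and is no sign of a lag by itself. All 8 genes stayed lower past the threshold when each of the 6 stationary libraries was left out. The rule that named these genes took the largest falls with no overlap between myricetin and DMSO libraries. The result could therefore hardly come out otherwise and does not test whether a single library deviated. A myricetin effect on these genes or on the oxygen in the flasks stays open and untested.

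For myricetin, 2.13 times as many genes were called in stationary as in exponential phase. The ratio was 1.4 without replicate 1 of the myricetin stationary group, and 3.32 and 3.84 without replicate 1 of the DMSO and replicate 2 of the myricetin exponential group. It was 1.67 without the 4 libraries numbered 3, and separate fits of 6 libraries called 1358 and 429 genes. The higher count totals of the stationary libraries could give more stationary calls, but with all libraries thinned to the smallest total the ratio was 2.05. Replicate shifts could hide exponential calls, but with the replicate number as a block the ratio was 2.26. Both tests argue against those explanations as the whole cause. Replicates of the more abundant genes spread more in exponential than in stationary phase. Their median SD of log2 CPM was 0.116 against 0.0919 with myricetin and 0.0918 against 0.0832 with DMSO. The part of this spread in the ratio was not tested, nor was a longer exposure or a different physiological state in stationary phase.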

How the results depend on the processing

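The thinned libraries, the omission of the 4 libraries numbered 3, the heme list without *hemP* and the iron list without *hemP*, *bfr* and *hmuQ* were added after the data were seen. Counts of called genes stayed within 1.5 times of those reported, for all 5 comparisons, with RLE factors, library totals, no filter, the 10 CPM filter, DESeq2, no structural RNA genes, thinned libraries and the additive replicate block, and for the 4 pairwise comparisons with only 6 libraries. Requiring at least 2-fold left 65 and 201 genes for myricetin in exponential and stationary phase, 268 and 298 for phase with DMSO and with myricetin, and 114 for the interaction, by construction. With the replicate number as a block (paired fit) the counts were 527, 1191, 1610, 1744 and 516 in that order. The paired fit by culture, which uses more parameters, gave 390 for the interaction, 1480 for phase with DMSO and 1621 with myricetin. The block by number ended the calls of 8 of the named gene results, among them *trxB*, *hemH* and *dddP* in exponential phase and *rpoH* in stationary phase, ended no list's call and brought the iron regulator list (phase with DMSO, adjusted p = 0.0492) and the RNA polymerase list (phase with myricetin, adjusted p = 0.0404) past the threshold, which an estimated correlation did not (0.503 and 0.268). Without the 4 libraries numbered 3 the stationary myricetin count was 719 and the interaction count 216, with 2 libraries left in each group. Leaving out each library in turn gave 348 (without myricetin replicate 2) to 681 in exponential phase, 829 (without myricetin replicate 1) to 1364 in stationary phase, 1402 to 1539 and 1556 to 1808 for phase, and 379 (without stationary myricetin replicate 3) to 688 for the interaction. Runs numbered 45 and 96 with at least 3 genes, and 11 and 20 with at least 6, in exponential and stationary phase, by construction. No gene or list result past the threshold turned direction. Library totals turned the balance of calls for myricetin in exponential phase (351 higher, 243 lower) and shifted it for the interaction (200 and 385). For phase with myricetin, library totals (744 and 1185), RLE factors, no filter and DESeq2 turned it. The near-even balance for myricetin in stationary phase (626 and 619) turned with several settings. Among them were library totals (602 and 619), no filter (620 and 624), the replicate block (587 and 604) and removal of structural RNA genes (573 and 653). Of 183 called gene results 144 kept call and direction in all alternatives run for them, and 39 lost the call in at least 1, all 39 of these when a library was left out and 14 also under another setting. An estimated correlation ended 30 list calls, leaving out a library 3 (in 5 fits), and leaving out *hemP* the exponential heme call (adjusted p = 0.883). Without *hemP*, *bfr* and *hmuQ* the iron list's 3 calls ended (adjusted p = 0.856 and 0.849 for myricetin in exponential and stationary phase and 0.186 for phase with myricetin). Where no setting's construction shows the cause, the cause was not tested.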

Other observations

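The genes in this paragraph have no symbol and were chosen after their values were seen. The largest rises with myricetin at both phases were in the neighbouring plus-strand genes PVU19_RS13610, PVU19_RS13615, PVU19_RS13620 and PVU19_RS13625 (2766865 to 2770622). Their log2 fold changes were 6.63 ± 0.14, 6.42 ± 0.14, 6.24 ± 0.19 and 6.23 ± 0.15 in exponential phase and 7.28 ± 0.14, 7.44 ± 0.14, 7.37 ± 0.18 and 7.28 ± 0.14 in stationary phase. The gene on the other strand beside them, PVU19_RS13605 (2764612 to 2766621), rose by 3.76 ± 0.11 and 4.68 ± 0.12. PVU19_RS08060 (1628973 to 1629266) rose by 4.89 ± 0.18 and 4.87 ± 0.16, while its neighbour on the other strand, PVU19_RS08065, changed by -1.90 ± 0.16 and -3.51 ± 0.17. PVU19_RS16440 (3318459 to 3319475) rose by 3.81 ± 0.19 and 3.97 ± 0.19 and was among the most abundant transcripts, at 25199 CPM in replicate 1 of the myricetin exponential group against 1596 CPM in replicate 1 of its DMSO group. All of these passed edgeR's test at both phases.

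Cobalamin biosynthesis genes, a list written from symbols before any test, had 7 of 17 members higher with myricetin in stationary phase and 0 called in exponential phase, with camera adjusted p = 0.171 and 0.82. The stationary count ran from 4 to 8 when 1 library was left out. Of 16 genes of lipopolysaccharide transport and the outer membrane 5 were higher in stationary phase (adjusted p = 0.385), and of 10 histidine genes 5 were lower (adjusted p = 0.171). Both counts ran from 3 to 5 when 1 library was left out.

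For the segment from 2950001 to 3150000, the tests on DNA copies and on scaling were chosen after the result was seen. The segment held 26.63% of all genes called lower in exponential phase and 21.65% of those in stationary phase. At least 127 segment genes, against 134, were called lower in stationary phase with library totals, RLE factors and thinned libraries. In exponential phase 79, against 90, were called lower with library totals. A scaling factor shifts all genes of a library alike, so these counts could hardly come out otherwise and do not test why lower genes lie together. Fewer copies of the whole segment are argued against by the 8 *cob* genes inside it, whose stationary median was 0.27 (range 0.00 to 0.48) against -0.62 for the rest. In exponential phase the gap was smaller, with medians of -0.08 for the *cob* genes and -0.33 for the whole segment. Fewer copies of separate parts cannot be told apart from shared regulation: in the longest unbroken stretch, 28 genes on both strands from PVU19_RS14715 to PVU19_RS14855, the SD of the log2 changes was 0.231 against a median SE of 0.119, and no DNA was measured.

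A hypothesis chosen after the values were seen is that myricetin gives a response like that to low iron, with *sufB*, *sufC*, *iscR* and *hmuQ* higher and *mbfA* and *bfr* lower. Of 12 tests on these 6 genes, 8 passed in that direction, 2 of them on *hmuQ*, one of the genes that prompted the hypothesis, while *iscR* was lower at both phases (-0.66 ± 0.16 and -0.44 ± 0.15) and *bfr* was higher at both. *hemP* was not among the 6 genes. The tests were counted on values that prompted the hypothesis, and the genes did not move 1 way. They therefore cannot decide for or against the hypothesis, which stays open.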
